A study of Homo sapiens with 23 samples.

How the data were processed

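The data were RNA levels in primary endothelial cells, the cells that line blood vessels, grown from the vein (HUVE) and the arteries (HUAE) of human umbilical cords. Per the labels' protocols, vein and artery cells came from the same cord, and the cells of each vessel were divided right after isolation between 3% oxygen (physiological chronic normoxia, PCN) and 21% oxygen (standard culture normoxia, SCN) and expanded for 20 to 25 days. RNA was labelled with biotin and each sample was hybridised to its own Affymetrix U133 Plus 2.0 array, a 1-colour array on which several short probes form a probe set for a transcript. In all, 23 arrays were used: 6 of HUAE at 21% oxygen, 6 of HUAE at 3%, 6 of HUVE at 21% and 5 of HUVE at 3%. The protocol for extraction counts 6 pairs for each vessel and 24 arrays, 1 more than was used here, and HUVE at 3% is the group with 5. The source names of the 3% samples mix the terms physiological and standard, so the groups and replicate numbers were taken from the sample titles. Each culture was counted as 1 replicate. No pair of arrays held identical or nearly identical values (0 pairs).

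The deposited table held probe set intensities on a log2 scale. The scale was read from the values, which ran from 1.89 to 14.7. The authors' processing is known only in part, since the submitters' processing notes name MAS5 without a version or a role, and the normalization between arrays is otherwise not given in the sources used here. The columns were already aligned, with medians between 5.66 and 5.74, and they were used as deposited. A shift of all transcripts in one condition would be hidden by such alignment. Intensities of different probe sets cannot be set against each other, and arrays carry no counts, so that the number of arrays limits the precision.

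Of 54675 probe sets, 62 were controls, 41097 carried 1 gene symbol in the platform annotation, 1801 carried several and 11777, controls included, carried none. Probe sets with several symbols or none were not named and were excluded from the gene tests. They were included only where every probe set was tested on its own. Symbols were updated by Entrez identifier through the RefSeq table of assembly GRCh38.p14, which matched 41043 probe sets. It was used for names only. No genome build is given in the sources used here, so no positions are printed. Probe sets of Y-linked genes and of the X inactivation transcript (59 probe sets) were left out. Probe sets were kept when their mean log2 intensity over all arrays lay above the 40th percentile (5.11). This cut was passed by 32768 non-control probe sets, with those excluded above also counted. Of the ones not excluded, each gene was represented by its probe set with the highest mean, giving 14277 tested genes.

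Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, in fits that held all 23 arrays, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Adjusted p-values of genes below are from limma. A gene past the threshold is referred to as called. The comparisons were 3% against 21% oxygen in artery cells and in vein cells, the mean of both oxygen effects, the difference between them, and vein against artery cells at each oxygen level. Replicates are cultures of different cords only as far as the titles' numbers and the protocols imply it.

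Whether equal replicate numbers mark the same cord is not stated in the labels, so the design fixed a rule: a term for the pair was kept where every same-numbered pair of arrays had a correlation above 0.1 between their deviations from the group means. In artery cells all 6 pairs passed (0.351 to 0.737, median 0.640), each 3% array correlated best with the 21% array of its own number, and the pair term was kept. Artery pairs of different numbers reached 0.360. All 6 pairs lay within 1 of the sets of arrays described below, which can also raise their correlation. Within the sets, same-numbered pairs had 0.267 to 0.470 in set A and 0.421 to 0.674 in set B. Different-numbered ones there reached at most -0.0257 and -0.0419. The artery fit held all 23 arrays and thereby also terms for the numbers of the vein arrays, which failed the rule. These leave the artery changes as they are but alter the spread shared by all arrays. A fit with pair terms for the artery arrays alone was therefore added after the data were seen. The other comparisons failed the rule and were fitted without a pair term.

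Gene lists were tested with limma's camera at its preset correlation of 0.01, two-sided, and adjusted over the 24 lists of each comparison. The lists covered the hypoxia response, glycolysis, oxidative phosphorylation, cholesterol synthesis, NRF2 antioxidant genes, cell cycle, p53 and senescence, VEGF and FGF angiogenesis, vascular tone, inflammation and adhesion, the interferon response, matrix and crosslinking, the TGF-beta and BMP response, the integrated stress response, jumonji and TET oxygenases, arterial markers, venous markers, HOX genes, pan-endothelial genes, and markers of smooth muscle, fibroblast or stroma, epithelium or amnion, leukocytes and erythroid cells. Camera was repeated with a correlation estimated from the data, and limma's fry was an alternative. For the lists in the oxygen comparisons, an exact two-sided test on the list mean of each array was added (sign flips of the 6 artery pairs, permutations of the 5 and 6 vein arrays).

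The comparisons, tests, lists, alternative settings and the choice of named genes were fixed before the data were examined. Genes were named when they were among the 6 largest rises or falls past the threshold that moved the same way in every pair (without pairs, whose group ranges did not overlap), when they were among up to 4 members with the smallest p in a list with a call, or when they stood in a short list of oxygen and vessel genes named whatever their result. Any other named gene was chosen after its values were seen, and these are members called in a list or genes singled out in the text.

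The fits were tested on simulated data in which 200 of 14277 genes were changed. For artery cells, 80.6% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered, and 5.56% of calls were false. For vein cells the shares were 67.2% and 91.0%, with 1.16% false. For the mean oxygen effect they were 80.6% and 100%, with 1.06% false. For vein against artery cells at 21% oxygen they were 68.7% and 91.0%, with 4.95% false, and at 3% oxygen 62.7% and 89.6%, with 10.2% false, above the nominal rate. In the simulation same-numbered arrays of a vessel shared a deviation, vein arrays included, so the shares for artery cells hold only if the vein numbers pair too. All simulated spreads came from the artery pairs, genes varied independently of each other, and no batches of arrays were simulated. The shares may therefore not hold for the real arrays. The difference between the oxygen effects was not simulated.

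The 18 spike-in probe sets, for transcripts added to the samples and not made by the cells, were used to divide the arrays by k-means clustering. The clustering was set to form 2 sets, so their number is not a result. Set A had 9 arrays, with mean spike-in log2 intensities of 10.955 to 11.416, and set B had 14, with 10.421 to 10.792. Set A held 3 artery arrays at each oxygen level, 2 vein arrays at 21% and 1 at 3%. The sets were treated as a batch in fits chosen after seeing the data. The alternative settings fixed earlier were quantile normalization, centring on the 75th percentile, offsets of 16 and 64 on the linear scale, other filters and probe set choices, other forms of the pair term, other variance models, a test without moderation, a fold minimum of 1.5 and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.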

Results

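RNA levels of 14277 genes were compared in endothelial cells of the umbilical vein (HUVE) and of the umbilical arteries (HUAE), each grown at 3% oxygen (PCN), near the oxygen level of these vessels before birth, or at 21% oxygen (SCN), the level of ordinary cell culture. The groups held 6 artery cultures at each oxygen level, 6 vein cultures at 21% and 5 at 3%. Values are log2 intensities, so a difference of 1 is a doubling. Changes are given on that scale with their standard error (SE), group levels as mean ± SD over arrays. Median intensities per array ran from 5.66 to 5.74. The median correlation of an array with the others ran from 0.954 to 0.980, and the lowest belonged to artery cells at 3% oxygen, replicate 1.

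The first question was how long-term growth at 3% instead of 21% oxygen altered artery cells. Of genes that cells switch on when oxygen is low, 13 of 38 rose, as did 7 of 22 genes of sugar breakdown, and 11 of 21 genes of the p53 and senescence programme fell. These numbers were 11, 5 and 6 with pair terms for the artery arrays alone. As lists these passed with the preset correlation and not with an estimated one (adjusted p = 0.115, 0.118 and 0.118 with an estimated correlation). AK4, a mitochondrial adenylate kinase, went from 7.77 ± 0.14 to 9.23 ± 0.24 (n = 6 and 6), a rise of 1.46 (SE 0.11, adjusted p = 8.92e-06). The largest rises were CLDN10, a tight junction protein (2.48, SE 0.18, adjusted p = 8.92e-06), and CXCL6, a chemokine that attracts neutrophils (2.31, SE 0.34, adjusted p = 0.00103). Among the largest falls were FAT3, an atypical cadherin (-1.94, SE 0.17, adjusted p = 1.68e-05), CD24, a surface glycoprotein (-1.83, SE 0.15, adjusted p = 1.24e-05), and SNAI2, a repressor that drives loss of cell contacts (-1.65, SE 0.18, adjusted p = 8.84e-05).

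In total 877 of 14277 genes were called in artery cells, 442 higher and 435 lower at 3% oxygen, and 85 of them changed at least 2-fold. This fit also held pair terms for the numbers of the vein arrays, which failed the pairing check. Holding such terms for the artery arrays alone, the fit called 417 genes, 195 higher and 222 lower, and 413 of them were among the 877. Other large rises were DAW1, a factor for dynein arms of cilia (2.08), GIPC2, a PDZ domain protein (1.91), CYB5R2, a cytochrome b5 reductase (1.81), and KRT19, a keratin (1.74). FLRT2 (-1.64) and FLRT3 (-1.56), both adhesion proteins, and TFEC, a transcription factor of the MiT family (-1.53), were among the other large falls. All of these moved the same way in 6 of 6 pairs. TFEC had a mean of 4.43 in artery cells at 3% oxygen, below the filter value of 5.11, so the size of its fall there is uncertain.

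**Figure D1:**
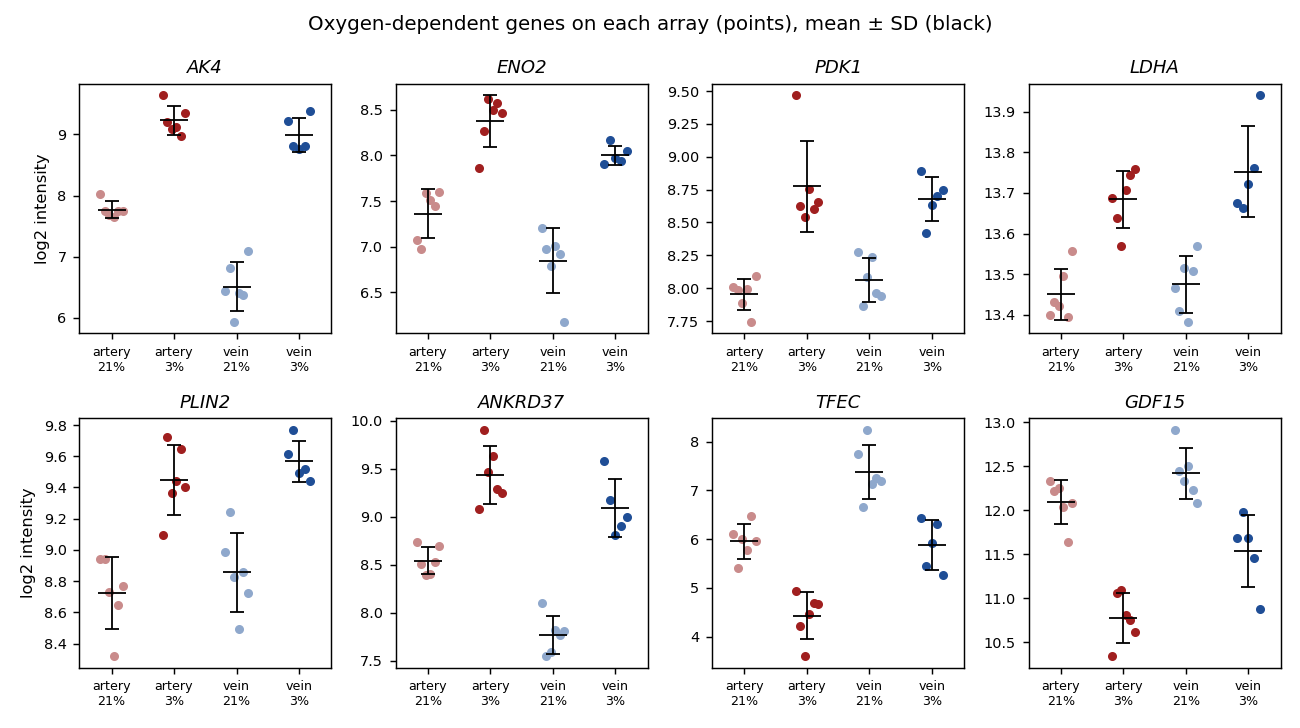
Log2 intensity (vertical axis) of 8 genes on each array (points) in artery and vein cells at 21% and 3% oxygen, with the mean and SD of each group in black. AK4, ENO2, PDK1, LDHA, PLIN2 and ANKRD37 were called higher and TFEC and GDF15 lower at 3% oxygen in the mean of both vessels. The vertical axes differ between genes and do not start at 0.

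Of 38 tested hypoxia response genes, 13 rose and 0 fell in artery cells (14 and 2 adjusted over the list alone), with a list mean of 0.28 (camera adjusted p = 6.02e-08, but adjusted p = 0.115 with an estimated correlation). The risers included ANKRD37 (0.89), PDK1, a kinase that inhibits pyruvate dehydrogenase (0.82), and PLIN2, a coat protein of lipid droplets (0.72). VEGFA, the main vascular growth factor (0.70), EGLN3, an oxygen-sensing prolyl hydroxylase (0.66), and SLC2A1, a glucose transporter (0.37, adjusted p = 0.0341), rose as well. ADM (-0.18, SE 0.15, adjusted p = 0.512) and NDRG1 (-0.24, SE 0.09, adjusted p = 0.125), which low oxygen induces in many cell types, did not pass. Of 22 glycolysis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them ENO2, an enolase (1.02), HK2, a hexokinase (0.64), and LDHA, a lactate dehydrogenase subunit (0.23). Their list mean was 0.24 (camera adjusted p = 2.31e-07, adjusted p = 0.118 with an estimated correlation). Both list means were positive in 6 of 6 pairs and within both spike-in sets (0.33 in set A and 0.23 in set B for hypoxia, 0.29 and 0.20 for glycolysis), and both reached the smallest exact sign-flip p that 6 pairs allow, 0.0312 (adjusted p = 0.107 over the 24 lists). The NRF2, p53 and senescence, inflammation, TGF-beta and leukocyte lists reached the same p. It therefore does not set the hypoxia and glycolysis lists apart.

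Of 21 p53 and senescence genes, 11 fell and 1 rose (14 and 1 adjusted over the list alone), with a list mean of -0.36 (camera adjusted p = 2.63e-07, adjusted p = 0.118 with an estimated correlation). CDKN2A, which encodes the cell cycle inhibitor p16 (-0.90), CDKN1A, which encodes p21 (-0.48), PHLDA3, a p53 target that curbs AKT (-0.49), and ZMAT3, a p53-induced RNA-binding protein (-0.58), fell. The riser was LMNB1 (0.32), a nuclear lamin whose loss marks senescent cells. CDKN2A had 3 probe sets, of which 1 moved the other way. Without the pair term 1 member of this list fell and 0 rose, with the list mean unchanged at -0.36. In the fit with pair terms for the artery arrays alone 6 fell and 0 rose, and CDKN1A (adjusted p = 0.0996), ZMAT3 (0.0818) and LMNB1 (0.127) did not pass.

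All 40 tested cell cycle genes had a positive change in artery cells and 9 were called higher (24 higher and 0 lower adjusted over the list alone). They included RRM2, a ribonucleotide reductase subunit (0.36), MCM2 (0.59) and MCM5 (0.45), parts of the replicative helicase, and CENPE, a kinetochore motor (0.50). MKI67, a proliferation marker, changed by 0.41 (SE 0.14) without passing (adjusted p = 0.0957). The list mean was 0.32 (camera adjusted p = 1.86e-13, adjusted p = 0.387 with an estimated correlation), and 0.30 within set A and 0.34 within set B. It was positive in 5 of 6 pairs, with an exact two-sided sign-flip p of 0.0625. Without artery replicate 1 at 3% oxygen 2 members were called, without the pair term 0, and with pair terms for the artery arrays alone 1.

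Inflammation and adhesion genes were 4 higher and 0 lower of 27 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0399, adjusted p = 0.523 with an estimated correlation). Besides CXCL6 they were IL33, an alarmin (1.60), TNFAIP3, a brake on NF-kB (1.08), and CXCL3, a chemokine (0.47). This list call ended without the pair term (adjusted p = 0.153) and with pair terms for the artery arrays alone (adjusted p = 0.159). Of 31 TGF-beta and BMP response genes 0 rose and 4 fell (0 and 10 adjusted over the list alone; camera adjusted p = 0.00119, adjusted p = 0.387 with an estimated correlation). These were SNAI2, SNAI1, a related repressor (-0.58), LTBP2, a latent TGF-beta binding protein (-0.45), and ID2, a BMP target (-0.43). Of 30 arterial markers 0 rose and 6 fell (1 and 11 adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.51 with an estimated correlation), among them SEMA3G, a class 3 semaphorin (-1.42), HES1, a Notch target (-0.83), SOX17, an arterial transcription factor (-0.63), and CXCR4, a chemokine receptor (-0.59). NRF2 antioxidant genes were 1 higher and 3 lower of 27 (2 and 10 adjusted over the list alone; camera adjusted p = 0.0293, adjusted p = 0.523 with an estimated correlation). GPX3, a glutathione peroxidase, rose (0.54), and FTL, the ferritin light chain (-0.36), PRDX2, a peroxiredoxin (-0.40), and EPHX1, an epoxide hydrolase (-0.66), fell.

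The other 16 lists did not pass as lists in artery cells, though 6 of them passed under at least 1 alternative setting. Angiogenesis genes moved both ways, 6 higher and 6 lower of 38 (7 and 12 adjusted over the list alone; camera adjusted p = 0.223). VEGFC, a lymphatic growth factor (0.90), VEGFA and FGF2 (0.75) rose, while PGF, the placental growth factor (-0.87), and FGFR3 (-0.50) fell. The VEGF receptors KDR (-0.33, SE 0.15, adjusted p = 0.221) and FLT1 (-0.21, SE 0.11, adjusted p = 0.259) did not pass. Of 29 vascular tone genes 1 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.137). NOS3, the endothelial nitric oxide synthase, went from 7.87 ± 1.0 to 8.89 ± 0.69 (1.02, SE 0.15, adjusted p = 0.00125). It did not pass without the pair term (adjusted p = 0.246) or with pair terms for the artery arrays alone (0.0771). EDN1, the precursor of the vasoconstrictor endothelin 1, fell (-0.54, adjusted p = 0.000227), although 1 of its 3 probe sets moved the other way. DDAH2, which degrades an inhibitor of nitric oxide synthases (-0.66), and KCNJ2, a potassium channel (-0.52), also fell. Matrix genes were 3 higher and 5 lower of 41 (5 and 8 adjusted over the list alone; camera adjusted p = 0.266). The protease ADAMTS1 (1.20) and the collagen crosslinkers LOX (0.85) and LOXL2 (0.51, with 2 of 4 probe sets moving the other way) rose, and the gelatinase MMP2 fell (-0.72).

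Oxidative phosphorylation genes were 0 higher and 0 lower of 52 in artery cells (0 and 0 adjusted over the list alone; camera adjusted p = 0.0696, and 0.0454 without the pair term). Their mean level was 10.8 in artery replicate 1 at 3% oxygen and 11.5 to 11.6 in the other 5 cultures of that group. Integrated stress genes were 2 higher and 1 lower of 31 (3 and 4 adjusted over the list alone), namely PSAT1, of serine synthesis (0.47), VLDLR, a lipoprotein receptor (0.62), and SESN2, a sestrin (-0.35). Cholesterol synthesis genes were 0 higher and 1 lower of 19, SC5D (-0.38), and HOX genes 0 higher and 1 lower of 22, HOXB5 (-0.45). Jumonji and TET oxygenases, enzymes that consume oxygen, were 1 higher and 0 lower of 24, the RNA demethylase ALKBH5 (0.34). Interferon response genes were 0 higher and 0 lower of 31 (4 and 0 adjusted over the list alone; camera adjusted p = 0.291). Their mean was 0.03 over all pairs, -0.22 within spike-in set A and 0.29 within set B (adjusted p = 6.7e-08), and 0.215 without artery replicate 1 at 3% oxygen (adjusted p = 6.53e-05). Venous markers were 0 higher and 1 lower of 17, NRP2 (-0.41). Pan-endothelial genes were 1 higher and 0 lower of 24, NOS3.

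Markers of other cell types moved in single genes in artery cells. Smooth muscle markers were 0 higher and 1 lower of 14, MYLK, a myosin light chain kinase (-0.69). Fibroblast or stromal markers were 2 higher and 1 lower of 15, with LOX and the collagen COL1A2 (0.71) up and the receptor PDGFRA (-0.31) down, and a list median of -0.07 against a mean of 0.09. Epithelial or amnion markers were 1 higher and 1 lower of 11, KRT19 and the junction protein JUP (-0.51), with a median of -0.05, a mean of 0.09 and a test direction downwards (camera adjusted p = 0.9). Leukocyte markers were 0 higher and 2 lower of 6, CORO1A (-0.65) and LAPTM5 (-0.57), with a median of 0.01 and a mean of -0.19. Erythroid markers were 0 higher and 1 lower of 6, CA1 (-0.28), whose mean at 3% oxygen (5.05) lay below the filter value.

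The artery count depended on the form of the pair term and on single arrays. With each array left out in turn it ran from 359 (without replicate 5) to 1180 (without replicate 3 at 21% oxygen). Without the pair term 246 genes were called, 105 higher and 141 lower, and 244 of them were among the 877. The fit with pair terms for the artery arrays alone, which gave 417, ended the calls of further genes above. These were RRM2 (adjusted p = 0.132), MCM2 (0.0868), MCM5 (0.15), IL33 (0.146), CXCL3 (0.401), SNAI1 (0.114), LTBP2 (0.0979), ID2 (0.0799), GPX3 (0.221), FTL (0.0668), PRDX2 (0.0512), EPHX1 (0.122), PSAT1 (0.103), VLDLR (0.159), SESN2 (0.0532), ALKBH5 (0.118), NRP2 (0.121), COL1A2 (0.129) and JUP (0.223). Within spike-in set A alone (3 pairs) 85 genes were called and within set B alone (3 pairs) 173.

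In vein cells the same question was put to a fit without a pair term, and hypoxia and glycolysis genes stood in front. AK4 went from 6.51 ± 0.40 to 8.997 ± 0.28 (n = 6 and 5), a rise of 2.49 (SE 0.16, adjusted p = 3.12e-09). GIPC2 (2.03, SE 0.33, adjusted p = 0.00469), CYB5R2 (1.88, SE 0.28, adjusted p = 0.00146) and ANKRD37 (1.32, SE 0.14, adjusted p = 3.09e-05) rose as well. TFEC fell from 7.37 ± 0.55 to 5.88 ± 0.51 (-1.49, SE 0.27, adjusted p = 0.0113). PTGS2, the inducible cyclooxygenase (-1.06, SE 0.23, adjusted p = 0.0441), and GDF15, a stress-induced cytokine (-0.88, SE 0.18, adjusted p = 0.0239), fell too.

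In all, 53 genes were called in vein cells, 35 higher and 18 lower at 3% oxygen, and 16 of them changed at least 2-fold. This number cannot be set against the 877 of artery cells, which came from a fit of another form. Without a pair term the counts were 53 in vein and 246 in artery cells. MPZL2, an adhesion protein (1.68), and TPD52, a vesicle trafficking protein (1.39), were among the other large rises. FBXL16, an F-box protein (-1.09), HS6ST2, a heparan sulfate sulfotransferase (-1.01), and ASXL3, a chromatin protein (-0.82), were among the other falls. Of the 38 hypoxia genes 5 rose and 0 fell (9 and 0 adjusted over the list alone), AK4, ANKRD37, PLIN2 (0.71), PDK1 (0.62) and BNIP3, a mitophagy receptor (0.58). Of the 22 glycolysis genes 3 rose and 0 fell (12 and 0 adjusted over the list alone), ENO2 (1.16), PDK1 and LDHA (0.28). Both lists held with an estimated correlation. The hypoxia list had a mean of 0.31 (camera adjusted p = 1.58e-14, adjusted p = 0.00015 with an estimated correlation) and the glycolysis list a mean of 0.28 (camera adjusted p = 2.67e-17, adjusted p = 0.00015 with an estimated correlation). The list means of the 5 and 6 cultures differed in an exact two-sided permutation test for both lists (p = 0.00216, adjusted p = 0.0259 over the 24 lists).

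**Figure D2:**
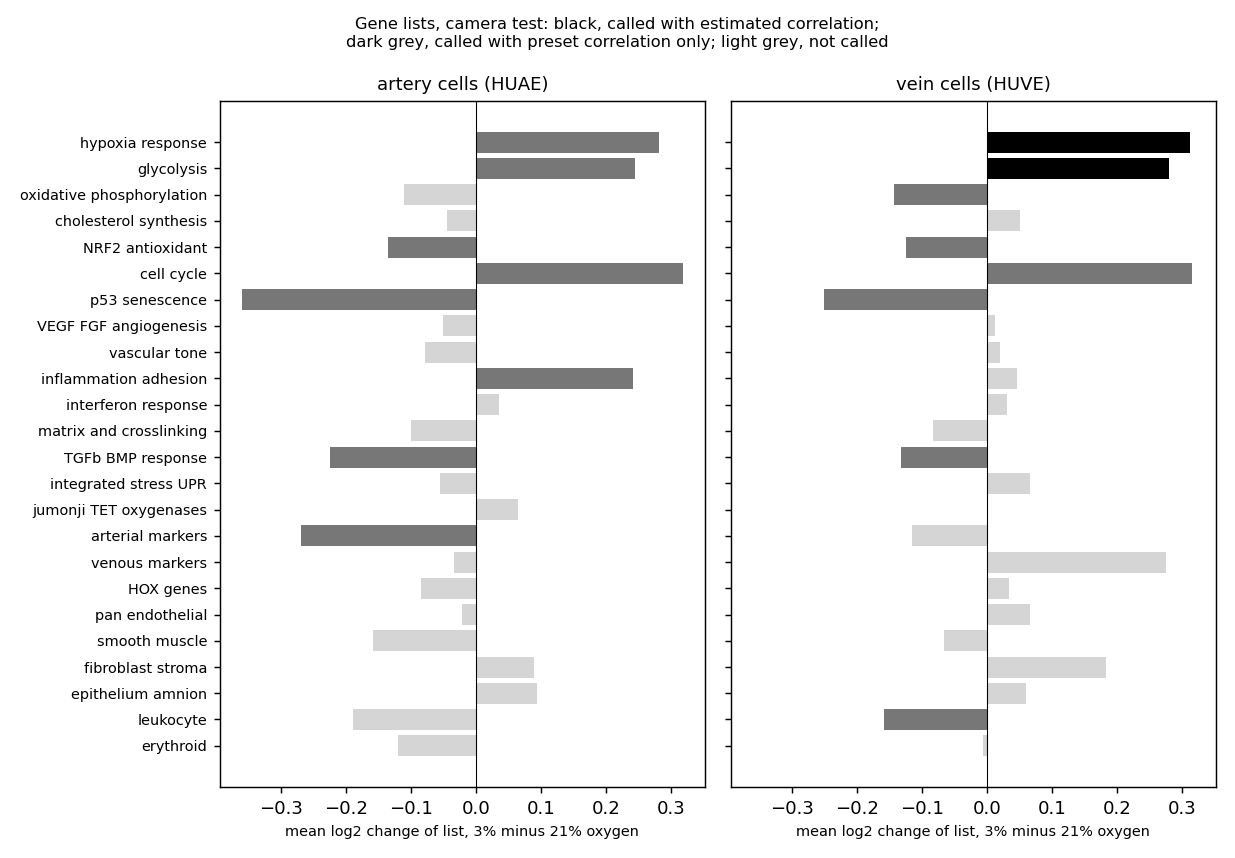
Mean log2 change at 3% against 21% oxygen of the tested members of 24 gene lists (horizontal bars) in artery cells (left) and vein cells (right). Black bars were called by camera with an estimated correlation, which held for the hypoxia and glycolysis lists of vein cells, dark grey bars with the preset correlation only, and light grey bars were not called.

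No cell cycle gene passed in vein cells (0 of 40 called, 0 adjusted over the list alone), yet all 40 changes were positive. Their mean was 0.31 (camera adjusted p = 1.32e-18, adjusted p = 0.138 with an estimated correlation), and the exact two-sided permutation p of the list means was 0.0541 (adjusted p = 0.185). MKI67 changed by 0.44 (SE 0.15, adjusted p = 0.457). The p53 and senescence list had 0 called members of 21 and a mean of -0.25 (camera adjusted p = 1.8e-05, adjusted p = 0.09 with an estimated correlation). NRF2 antioxidant genes had 0 called of 27 and a mean of -0.12 (camera adjusted p = 0.00448, adjusted p = 0.214 with an estimated correlation). TGF-beta and BMP response genes had 0 called of 31 and a mean of -0.13 (camera adjusted p = 0.0325, adjusted p = 0.249 with an estimated correlation). Leukocyte markers had 0 called of 6 and a mean of -0.16 (camera adjusted p = 0.0325, adjusted p = 0.138 with an estimated correlation), with CORO1A at -0.37. The calls of the TGF-beta and leukocyte lists both ended with quantile normalization (adjusted p = 0.055 for each).

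Oxidative phosphorylation genes, which encode the respiratory chain, had 0 called of 52 in vein cells and a mean of -0.14 (camera adjusted p = 0.00594, adjusted p = 0.814 with an estimated correlation). This list call came from 1 array. The list mean was 10.8 in vein replicate 5 at 3% oxygen and 11.5 to 11.6 in the other 4, and without that array it was 0.01 (adjusted p = 0.802). Glycolysis genes were also highest in this array (11.17 against 10.97 to 11 in the others). The remaining 16 lists were not called in vein cells, and outside the lists above their called members were PTGS2 among the vascular tone genes and MYLK (-0.81) among the smooth muscle markers. The other oxygen genes of interest did not pass in vein cells: NOS3 (0.49, SE 0.44, adjusted p = 0.987), VEGFA (0.38, SE 0.16, adjusted p = 0.672), SLC2A1 (0.31, SE 0.11, adjusted p = 0.412), EGLN3 (0.55, SE 0.17, adjusted p = 0.327) and FGF2 (0.13, SE 0.22, adjusted p = 0.995).

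The vein count was small and moved with single arrays and with the form of the fit. It ran from 21 to 76 genes when each array was left out in turn, and was 79 in the fit with pair terms for the artery arrays alone. It also rose with pair terms by the vein numbers, which the pairing check did not bear out. Within spike-in set B (4 cultures in each group) 24 genes were called, and set A held 1 vein array at 3% oxygen and gave 1 call.

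Averaged over both vessels, 633 genes were called, 330 higher and 303 lower at 3% oxygen, in a fit without a pair term for either vessel. With pair terms for the artery arrays, whose numbers passed the pairing check, 919 were called, 482 higher and 437 lower, and 622 of them were among the 633. The number rose further with terms by the vein numbers, which failed that check. AK4 (1.98, SE 0.11, adjusted p = 1.72e-10), ANKRD37 (1.10, SE 0.10, adjusted p = 5.7e-07) and ENO2 (1.09, SE 0.11, adjusted p = 2.59e-06) had a small error. Among called genes whose group ranges did not overlap in either vessel, the largest rises also included CLDN10 (2.07), GIPC2 (1.97) and CYB5R2 (1.85). DAW1 (1.64) and CDCP1, a transmembrane substrate of Src kinases (1.44), came next. The largest falls among genes without such overlap were TFEC (-1.51), EFNA2, an ephrin (-1.21), FBXL16 (-1.19), GDF15 (-1.10), MLLT11 (-0.93) and ABAT, a GABA transaminase (-0.90). In vein cells at 21% oxygen DAW1 (4.76), and in artery cells at 3% TFEC (4.43) and EFNA2 (4.98), lay below the filter value of 5.11. This leaves the size and order of these changes uncertain. With arrays centred on the 75th percentile the split of calls moved from 52.1% higher to 41.7% higher (606 calls).

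In this mean effect 14 of 38 hypoxia genes rose and 0 fell (15 and 0 adjusted over the list alone), and 10 of 22 glycolysis genes rose and 0 fell (12 and 0 adjusted over the list alone). Both lists held with an estimated correlation (adjusted p = 0.000571 for each). EGLN3 (0.60), VEGFA (0.54), SLC2A1 (0.34), HK2 (0.61) and P4HA1, a collagen prolyl hydroxylase subunit (0.40), were among them. The p53 and senescence genes were 1 higher and 5 lower of 21 (1 and 12 adjusted over the list alone). By camera this list also held with an estimated correlation (camera adjusted p = 6.33e-07, adjusted p = 0.0381 with an estimated correlation). In the exact tests on the list mean of each array it did not pass after adjustment in either vessel. The sign-flip p was 0.0312 in artery cells (adjusted p = 0.107) and the permutation p 0.0238 in vein cells (adjusted p = 0.114). CDKN2B, which encodes p15 (-0.98), TP53INP1 (-0.60), FAS, a death receptor (-0.46), and PHLDA3 (-0.43) fell. Cell cycle genes were 11 higher and 0 lower of 40 (31 and 0 adjusted over the list alone; camera adjusted p = 4.69e-19, adjusted p = 0.162 with an estimated correlation), with MKI67 (0.42), MCM3 (0.35) and RRM2 (0.39) among them.

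NRF2 antioxidant genes were 2 higher and 3 lower of 27 in the mean effect (camera adjusted p = 0.00436, adjusted p = 0.212 with an estimated correlation). GPX3 (0.62) and PRDX3 (0.18) rose, and HMOX1, the inducible heme oxygenase (-0.59), PRDX2 (-0.39) and FTL (-0.31) fell. TGF-beta and BMP response genes were 0 higher and 3 lower of 31 (camera adjusted p = 0.00752, adjusted p = 0.176 with an estimated correlation), SNAI2 (-1.08), LTBP2 (-0.43) and ID2 (-0.40). Arterial markers were 0 higher and 4 lower of 30 (camera adjusted p = 0.022, adjusted p = 0.839 with an estimated correlation), SEMA3G (-1.24), HES1 (-0.65), SOX17 (-0.54) and CXCR4 (-0.51). Oxidative phosphorylation genes had 0 called of 52 (camera adjusted p = 0.00752, adjusted p = 0.839 with an estimated correlation), and this list call ended without vein replicate 5 at 3% oxygen (adjusted p = 0.129) or without artery replicate 1 at 3% oxygen (adjusted p = 0.37).

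A further comparison asked whether the oxygen effect differed between vein and artery cells. Limma called 0 genes for this difference, and 190 had an unadjusted p under 0.05. As a share of the 14277 genes this is below the 0.05 that chance alone gives on average. The 190 are therefore no sign of differences, and the 0 calls do not show that the effects are equal. This fit had no pair term, because the numbers of the vein arrays failed the pairing check. Limma also called 0 with pair terms for the artery arrays alone, and with a term by the vein numbers too it called ALDH1A2, AK4 and MPZL2. Without these terms AK4 had the difference 1.03 (SE 0.23, adjusted p = 1), NOS3 -0.53 (SE 0.61, adjusted p = 1) and VEGFA -0.32 (SE 0.22, adjusted p = 1), each as vein effect minus artery effect. The calls of the vessels overlapped: 27 genes were called higher in both (1.08 in independent lists of these sizes), 14 lower in both (0.548 in independent lists), and 0 in opposite directions. Of the 442 genes higher in artery cells 431 had a positive change in vein cells, and of the 435 lower 418 had a negative one. Across the 14277 genes, which are not independent replicates, the effects correlated with r = 0.707 (Spearman's rho 0.602). Vein and artery cells of a cord share a donor, and this can raise the correlation.

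**Figure D3:**
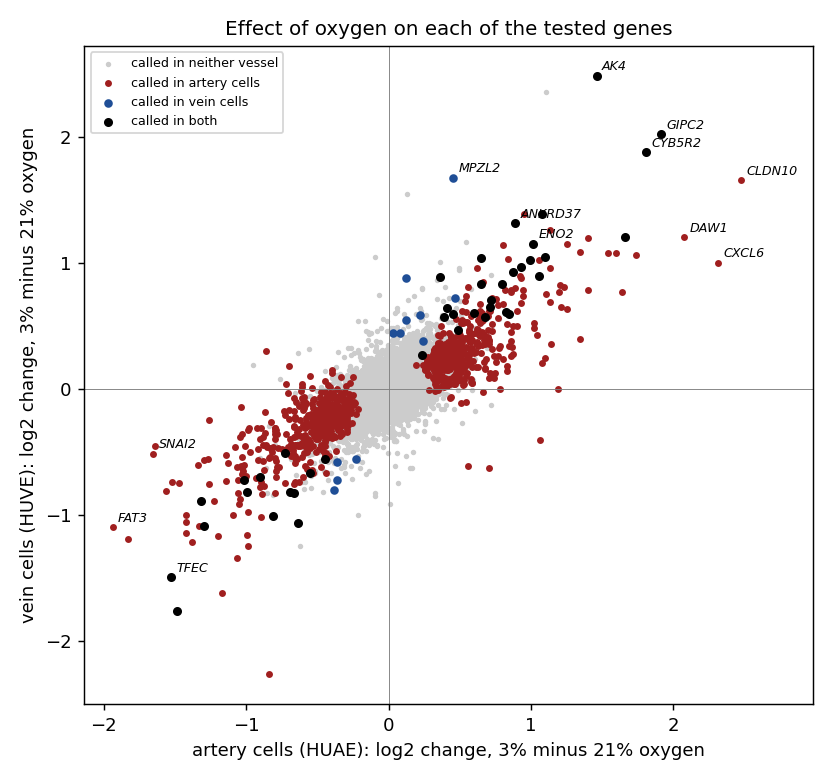
Log2 change at 3% against 21% oxygen of each of 14277 genes in artery cells (horizontal axis) and vein cells (vertical axis). Grey points were called in neither vessel, red in artery cells, blue in vein cells and black in both. The genes in black, 27 called higher in both and 14 lower in both, changed in the same direction in both vessels, and the correlation across genes was 0.707.

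Vein and artery cells were then compared at each oxygen level, to ask which differences of vessel identity these cultures kept. The arterial genes GJA5 and HEY2 were far lower in vein cells at both levels. GJA5, a gap junction protein of arteries, had a level of 11.7 ± 0.27 in artery cells and 6.45 ± 0.18 in vein cells at 21% oxygen (-5.20, SE 0.33, adjusted p = 2.38e-10) and a difference of -4.93 at 3%. HEY2, a Notch target needed for arterial fate, differed by -4.32 at 21% oxygen and -4.73 at 3%. In vein cells ADAMTS18, a secreted protease, was higher by 5.31 (SE 0.30, adjusted p = 2.81e-11) at 21% and 5.56 at 3%. ALDH1A2, which makes retinoic acid, was higher by 4.43 at 21% oxygen (SE 0.24, adjusted p = 1.58e-11) and by 5.57 at 3%. ADAMTS18 in artery cells at 3% oxygen (5.04) and ALDH1A2 there at both levels lay below the filter value of 5.11.

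Neither vessel comparison held a pair term, because the numbers failed the pairing check. Both counts below rose with a block by number across all groups. At 21% oxygen 697 genes were called, 313 higher and 384 lower in vein cells, with 253 differing at least 2-fold. At 3% oxygen 828 genes were called, 402 higher and 426 lower, with 315 differing at least 2-fold. Of these, 246 were higher in vein cells at both levels (8.81 in independent lists) and 279 lower at both (11.5 in independent lists), with 0 in opposite directions. Across genes the differences at the 2 levels correlated with r = 0.898 (Spearman's rho 0.656). The cells of each vessel were divided between the oxygen levels, so differences between donors or cultures can recur in both comparisons. This can raise the overlap and the correlation, and was not tested. Other large differences towards vein cells, given for 21% and 3% oxygen, were SFRP1, a Wnt antagonist (3.75 and 3.67), PTGS1, the constitutive cyclooxygenase (3.73 and 3.88), CDH11, a cadherin (3.50 and 4.38), and ZNF462, a zinc finger protein (3.37 and 3.43). Towards artery cells were CPM, a carboxypeptidase (-4.14 and -3.97), and NKX2-3, a homeobox factor (-4.07 and -3.92), with MPZL2 (-4.13) at 21% oxygen and SEMA3C, a semaphorin (-4.15), at 3%. ALDH1A2 (4.01 at 21% oxygen) and ZNF462 (4.26) in artery cells and NKX2-3 (3.21) and SEMA3C (3.83) in vein cells lay below the filter value, so these sizes are uncertain.

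Of 30 arterial markers 11 were lower and 2 higher in vein cells at 21% oxygen (13 and 3 adjusted over the list alone; camera adjusted p = 7.48e-09, adjusted p = 0.334 with an estimated correlation). At 3% oxygen 9 were lower and 2 higher (13 and 3 adjusted over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.792 with an estimated correlation). The Notch ligand DLL4 (-1.76 and -1.26), the ephrin EFNB2 (-1.15 and -1.05), IGFBP3 (-2.59 and -2.10) and SLC45A4 (-2.58 and -2.57) were lower in vein cells at both levels. HES1, a Notch target, went against its list and was higher in vein cells (0.77 and 1.14). Of 17 venous markers 3 were higher and 1 lower in vein cells at 21% oxygen (9 and 2 adjusted over the list alone; camera adjusted p = 0.000148, adjusted p = 0.334 with an estimated correlation), and 7 and 1 at 3% (10 and 1 adjusted over the list alone; camera adjusted p = 3.66e-06, adjusted p = 0.09 with an estimated correlation). NRP2, a receptor for VEGFC and semaphorins (1.65 and 2.08), EMCN, a sialomucin (1.23 and 1.59), and the interleukin receptor IL1R1 (1.42 and 1.40) were higher. EPHB4, the venous ephrin receptor, was called at 3% oxygen (0.69, adjusted p = 0.0159) and not at 21% (0.55, adjusted p = 0.0621). ADGRG6, an adhesion receptor on the venous list, was lower in vein cells (-1.46 and -1.02).

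**Figure D4:**
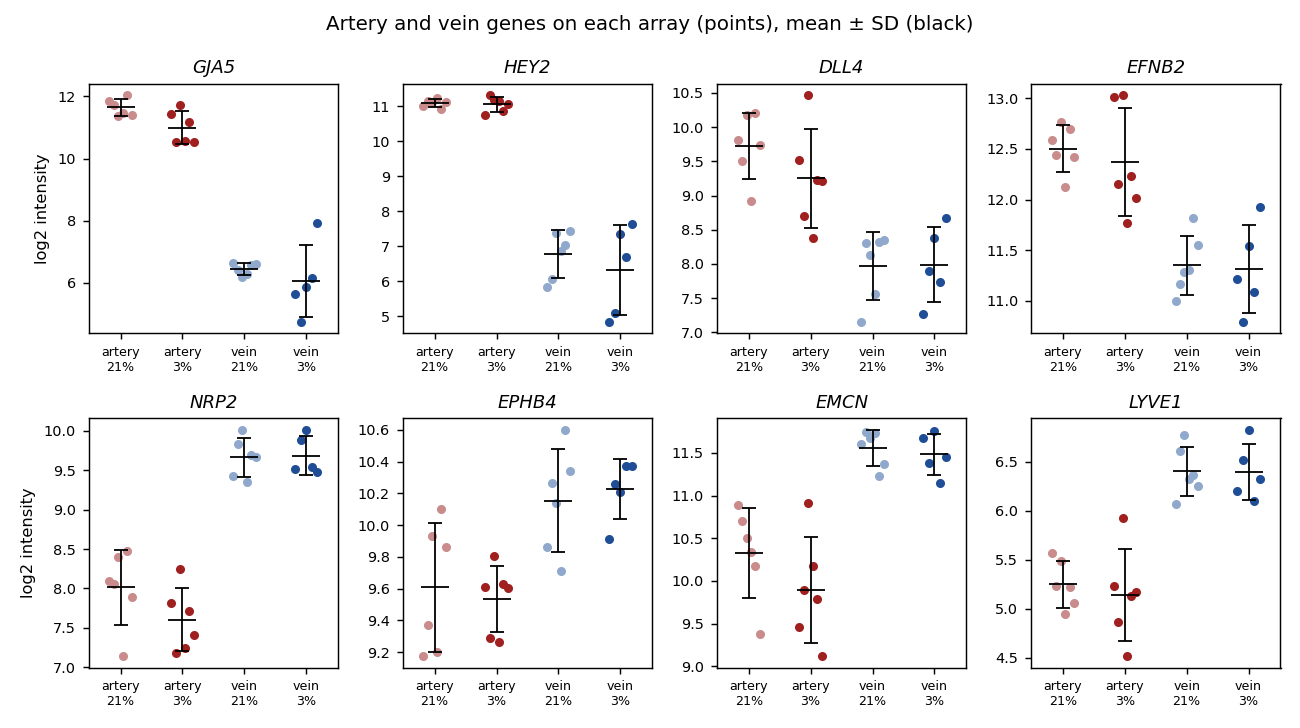
Log2 intensity (vertical axis) of 4 arterial genes (upper row) and 3 venous genes with the lymphatic and venous receptor LYVE1 (lower row) on each array (points), with the mean and SD of each group in black. GJA5 had a mean of 11.7 in artery cells and 6.45 in vein cells at 21% oxygen. The vertical axes differ between genes and do not start at 0.

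Of genes shared by endothelial cells, PECAM1 (-0.11, SE 0.19, adjusted p = 0.942) and CDH5 (0.22, SE 0.14, adjusted p = 0.609) did not pass at 21% oxygen, nor did VWF (1.04, SE 0.39, adjusted p = 0.165). Pan-endothelial genes were 1 higher and 2 lower of 24 at 21% and 2 higher and 1 lower at 3%. Their list means were 0.27 and 0.35 towards vein cells (camera adjusted p = 0.105 and 0.0945). The list passed within spike-in set B at both levels (adjusted p = 0.0305 and 0.041), with a replicate block by the numbers, which failed the pairing check, and at 3% oxygen without artery replicate 1 (0.0329) or with the batch term (0.0442). Called members included the lymphatic and venous receptor LYVE1, higher (1.15 and 1.25), and the VEGF receptor FLT1, lower (-0.96 and -0.86). Vascular tone genes went both ways, 5 higher and 3 lower of 29 at 21% oxygen and 6 higher and 4 lower at 3%. PTGS1 and the endothelin receptor EDNRB (1.64 and 1.87) were higher and the subunits of the nitric oxide receptor GUCY1A1 (-2.51 and -2.34) and GUCY1B1 (-2.19 and -2.08) were lower. Angiogenesis genes were 2 higher and 3 lower of 38 at 21% and 5 higher and 5 lower at 3%, with the guidance cue SEMA3A lower (-1.68 and -2.20). HOX genes, which carry positional identity, were 2 higher and 3 lower of 22 at 21% and 2 higher and 1 lower at 3%. HOXA2 (1.11 and 1.17) and HOXD8 (0.52 and 0.57) were higher, HOXB4 (-0.82 and -0.66) was lower, and HOXD9 did not pass (0.14 and 0.26). EDNRB (4.78 at 21% oxygen) and HOXA2 (4.93) lay below the filter value in artery cells.

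Interferon response genes were 0 higher and 3 lower of 31 in vein cells at 21% oxygen (camera adjusted p = 0.000119, adjusted p = 0.68 with an estimated correlation) and 0 and 2 at 3% (camera adjusted p = 0.000159, adjusted p = 0.792 with an estimated correlation). BST2, an antiviral tether, was lower at both levels (-1.40 and -1.38), and IFI27 (-1.70) and IFI44 (-0.69) were called at 21%. The list difference at 21% oxygen was -0.32 over all arrays and -0.01 within spike-in set B (adjusted p = 0.591). Jumonji and TET oxygenases had 0 called of 24 at 21% oxygen and a list mean of 0.12 (camera adjusted p = 0.0464, adjusted p = 0.68 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0668). Of the hypoxia genes, AK4 (-1.26), ANKRD37 (-0.77) and SLC2A1 (-0.45) were lower in vein cells at 21% oxygen, and SLC2A1 (-0.50) at 3%. HMOX1 was higher in vein cells at both levels (1.78 and 1.65).

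For p53 and senescence genes the list median (0.10) and mean (-0.14) differed in sign at 21% oxygen, with 0 higher and 3 lower of 21, among them CDKN2A (-1.52). At 3% oxygen 1 was higher and 2 lower, with a median of 0.11 and a mean of -0.03.

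Markers of stromal cells went both ways between the vessels. Of 15 fibroblast or stromal markers 2 were higher and 3 lower in vein cells at 21% oxygen and 3 higher and 3 lower at 3%. DCN, a proteoglycan (1.49 and 2.04), and TWIST2, a mesenchymal transcription factor (1.76 and 1.64), were higher, and FAP, a fibroblast surface protease (-3.72 and -3.49), and S100A4 (-3.37 and -3.28) were lower. Smooth muscle markers were 1 higher and 1 lower of 14 at each level, the pericyte gene RGS5 (1.48 and 1.98) and the channel subunit KCNMB1 (-1.21 and -1.08). Within spike-in set A 200 genes were called at 21% oxygen and 146 at 3% (1 vein array), and within set B 478 and 661.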

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

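Tests chosen only after the result was seen were those of stromal cells, the fits within the spike-in sets, and the splits of artery cells without the pair term or with pair terms for the artery arrays alone. In the 192 combinations of a group with a list, a gene or the correlation of its arrays with the others that were examined, 14 had 1 array far from the others of its group, measured as its gap to the nearest array over the range of the group. Chance gives about 1 in 20, or 9.6.

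Artery replicate 1 at 3% oxygen stood apart in several respects. Its median correlation with the other arrays was 0.954, against 0.972 to 0.977 (gap 0.792 of the range). Its oxidative phosphorylation genes were at 10.84 against 11.53 to 11.63 (gap 0.865), its epithelial markers at 7.5 against 7.829 to 7.939 (gap 0.748), and PDK1 at 9.47 against 8.542 to 8.751 (gap 0.775). Vein replicate 5 at 3% oxygen had the same direction in oxidative phosphorylation genes, 10.75 against 11.46 to 11.59 (gap 0.84). Its glycolysis genes were at 11.17 against 10.97 to 11 (gap 0.864), its integrated stress genes at 10.1 against 9.901 to 9.952 (gap 0.749), and EGLN3 at 7.066 against 6.131 to 6.358 (gap 0.757).

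In artery replicate 3 at 3% oxygen p53 and senescence genes were at 9.54 against 9.178 to 9.265 (gap 0.76) and ADM at 10.33 against 9.701 to 9.905 (gap 0.673). HMOX1 was at 9.702 in artery replicate 3 at 21% oxygen, against 8.431 to 8.743 (gap 0.754). Pan-endothelial genes were at 10.63 in vein replicate 1 at 3% oxygen, against 11.08 to 11.23 (gap 0.741). VWF was at 10.77 in vein replicate 1 at 21% oxygen, against 12.32 to 13.06 (gap 0.676), and interferon response genes were at 6.84 in vein replicate 3 at 21% oxygen, against 7.014 to 7.106 (gap 0.653).

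The oxygen effect differed between vein and artery cells by camera at its preset correlation in 5 lists, each more positive in vein cells and none past the threshold with an estimated correlation. They were integrated stress genes (difference 0.12, adjusted p = 0.0236, adjusted p = 0.527 with an estimated correlation), cholesterol synthesis (0.10, adjusted p = 0.0257, adjusted p = 0.527 with an estimated correlation), vascular tone (0.10, adjusted p = 0.0345, adjusted p = 0.557 with an estimated correlation), venous markers (0.31, adjusted p = 0.0345, adjusted p = 0.557 with an estimated correlation) and erythroid markers (0.11, adjusted p = 0.0345, adjusted p = 0.527 with an estimated correlation). Without vein replicate 5 at 3% oxygen 4 of these calls ended: vascular tone (adjusted p = 0.112), integrated stress (0.0749), venous markers (0.0749) and erythroid markers (0.0534). All 5 ended with fry (adjusted p = 0.82 each). Other lists passed only under an alternative, 11 in all, and not all towards vein cells. Inflammation genes were more negative in vein cells (-0.19, adjusted p = 0.0507), and passed with quantile normalization (0.044), with pair terms for the artery arrays alone (0.0394) and without artery replicate 1 at 3% oxygen (0.021). Oxidative phosphorylation genes passed in opposite directions, -0.156 without artery replicate 1 at 3% (adjusted p = 0.000114) and 0.12 without vein replicate 5 at 3% (adjusted p = 7.26e-05).

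For each count of called genes, other splits of the same arrays into groups of the same sizes were fitted, and the counts below include the real split. In artery cells 1 of the 32 splits that part every pair gave as many as the real 877, and the highest other gave 107. This argues against chance, though 1 of 32 is the smallest share these splits can give. With pair terms for the artery arrays alone the real split gave 417 and the highest other 1. Without the pair term the real split gave 246, and 3 of 100 splits gave as many. The highest, 2426, was the split along the spike-in sets, so the arrays carry a structure other than oxygen, and within the sets the oxygen counts were 85 and 173. In vein cells 1 of 100 splits gave as many as the real 53, with 5 the highest other, which argues against chance. Since the real split is counted, 1 of 100 is the smallest share that 100 splits can give. For the mean effect 2 of 100 gave as many as the real 633. This share argues against chance, but these splits were drawn within each vessel without regard to the artery pairs. The highest other gave 1717, which points to a structure of the arrays. For vein against artery cells 1 of 100 splits gave as many as the real 697 at 21% oxygen (highest other 26). At 3% oxygen 1 of 100 gave as many as the real 828 (highest other 392), and both shares argue against chance. For the difference between the oxygen effects limma called 0 genes, and the highest other split gave 2. An unadjusted p under 0.05 was found for 190 genes, a smaller share than chance alone gives on average. With a real count of 0 all 100 splits give as many by construction, so this says nothing about chance.

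The rise of cell cycle genes at 3% oxygen in both vessels was weighed against technical causes. Batches of arrays as the whole cause are argued against by its value within spike-in set B of the vein cells (0.26), and artery replicate 1 as the cause by its value without that replicate (0.335). The authors' normalization stays open. With arrays centred on the 75th percentile the mean over both vessels went from 0.317 to 0.293, but this shifts all genes of an array alike, and the 75th percentiles spanned only 0.114, so the test could not have ended the rise. A shift of all transcripts would be hidden in the aligned values. Chance differences between cultures stay open as well, with an exact two-sided sign-flip p of 0.0625 in artery cells (positive in 5 of 6 pairs) and an exact permutation p of 0.0541 in vein cells. In the mean effect over both vessels the list passed with fry (adjusted p = 0.00842) and not by camera with an estimated correlation (adjusted p = 0.162). The rise may be an effect of oxygen, but at the level of cultures it did not pass in either vessel.

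The stromal genes that differ between the vessels could come from stromal cells in the cultures. The test used the stromal genes COL1A1, COL1A2, COL3A1 and DCN. LUM was also named for it but was not among the tested genes. The criterion was changed after the values were seen, to leave the question open where members go both ways. This was so, and stromal cells in the vein cultures and in the artery cultures both stay open. The medians lay towards vein cells (0.672 and 0.984), with COL3A1 (2.22 and 2.85 at 21% and 3% oxygen) and DCN (1.49 and 2.04) towards vein cells and COL1A2 (-1.14 and -1.22) and COL1A1 (-0.15 and -0.07) the other way. A difference between the endothelial cells of the vessels was not tested apart from this.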

How the results depend on the processing

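Settings chosen after seeing the data were the spike-in batch as a term, the fits within spike-in set A or B and the replicate block for artery arrays only. Where a value moved below, the cause was not tested unless a reason is given. With quantile normalization, centring on the 75th percentile, offsets of 16 and 64, the other filters, the mean of probe sets, no trend and robust variance, the 6 counts of called genes stayed within 1.5 times their reported values. Centring on the 75th percentile gave 606 for the mean effect and moved its share of higher calls from 52.1% to 41.7%.

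For genes named in the text, 11763 results under an alternative kept their direction and side of the threshold, 1141 no longer passed, 40 newly passed and 38 reversed. None of the reversed ones was called. For lists the numbers were 1241, 86, 61 and 4.

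Without the pair term the artery count fell to 246 (105 higher, 141 lower, 244 shared with the 877). A replicate block for artery arrays only gave 417, 919 for the mean effect, 79 in vein cells and 0 for the difference. A replicate block by the labels' numbers, which the pairing check did not bear out for these comparisons, gave 314 in vein cells, 1765 for the mean effect, 3 for the difference and 1294 for the vessels at 3% oxygen. The 3 genes were ALDH1A2, AK4 and MPZL2 (adjusted p = 0.036, 0.036 and 0.0436, and 1 without the block). In the check, 3 of 5 vein pairs passed (lowest -0.265), 5 of 6 vein and artery pairs at 21% oxygen (lowest 0.0684) and 3 of 5 at 3% (lowest -0.048). One block across the 4 groups gave 245 in vein cells, 1651 for the mean effect, and 1178 and 1535 for the vessels at 21% and 3% oxygen. A random replicate block gave 162 in vein cells and 1693 for the mean effect.

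Testing every probe set, with those of several symbols or none included, gave more tests and 1417 calls in artery cells, 1220 for the vessels at 21% oxygen and 1489 at 3%. With only the arrays of the comparison 26 were called in vein cells and 548 for the vessels at 3%. For the mean and the difference this setting equals all arrays and gives no value. A change of at least 1.5-fold, a stricter rule by construction, left 316 in artery cells and 183 for the mean effect. The test without moderation left 39 in artery cells, 7 in vein cells and 325 for the vessels at 3% oxygen. In these comparisons it also used only the arrays of the comparison, so the effect of moderation alone cannot be read from it.

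The spike-in batch as a term, without the block, gave 1346 for the mean effect. Set A alone, with fewer arrays, gave 85 in artery cells, 1 in vein cells, 30 for the mean effect, 200 for the vessels at 21% oxygen and 146 at 3%. It held 1 vein array at 3% oxygen, assumed to vary like the other groups. Set B alone gave 173, 24 and 230 for artery cells, vein cells and the mean effect.

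With each array left out in turn the artery count ran from 359 to 1180. Without replicate 5 at either oxygen level it was 359, without replicate 2 394 (21%) and 396 (3%), without replicate 4 506 and without replicate 6 562. The vein count ran from 21 to 76. It was 22, 21, 31 and 24 without replicates 1, 2, 3 and 4 at 21%, and 31, 22 and 23 without replicates 1, 4 and 5 at 3%. The mean effect ran from 401 (without vein replicate 4 at 3%) to 993 (without artery replicate 3 at 3%), the difference stayed at 0, and the vessels ran from 560 to 927 at 21% and 620 to 907 at 3%.

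Reversals on leaving out an array concerned genes near 0, whose full ranges follow. In the difference between oxygen effects they were -0.055 to 0.142 for MKI67, -0.017 to 0.15 for NDRG1, -0.005 to 0.236 for FLT1, -0.363 to 0.028 for HMOX1 and -0.113 to 0.002 for SLC2A1. ADM ran from -0.096 to 0.018 in the mean effect, KDR from -0.251 to 0.109 in vein cells, and PECAM1 from -0.131 to 0.112 between the vessels at 3% oxygen. With the batch term MKI67 was -0.004 in the difference. Within set A, EGLN3 was 0.21 and HMOX1 0.105 in the difference, and HOXD9 -0.026 between the vessels at 21%. Within set B, ADM was 0.129 in artery cells, -0.03 in vein cells, 0.049 in the mean and -0.159 in the difference. There MKI67 (-0.126), NDRG1 (-0.08) and SLC2A1 (0.008) reversed in the difference, and PECAM1 between the vessels (0.003 at 21%, 0.076 at 3%).

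The oxidative phosphorylation list in vein cells reversed without vein replicate 5 at 3% oxygen (0.011, adjusted p = 0.802), was -0.143 without artery replicate 1 at 3%, the other array left out for lists, and reversed within set A (0.066). NRF2 genes in vein cells were at -0.004 within set A, with the test direction turned (adjusted p = 0.91), and erythroid markers at -0.016 in the difference within set B. List calls that ended in artery cells included NRF2 (adjusted p = 0.168) and TGF-beta genes (0.417) within set A, and inflammation genes with the batch term (0.187) and without the pair term (0.153). In vein cells the leukocyte call ended without vein replicate 5 at 3% oxygen (0.067). With fry 21 list calls ended. They included cell cycle (adjusted p = 0.0517), inflammation (0.116) and arterial markers (0.0637) in artery cells, cell cycle (0.0965) and p53 and senescence (0.0663) in vein cells, arterial markers in the mean effect (0.303) and at 3% oxygen (0.0618), and the 5 lists of the difference. With an estimated correlation 31 ended. Lists also newly passed: 6 in artery cells, 2 in vein cells, 2 for the mean, 11 for the difference, and 7 and 4 for the vessels at 21% and 3%. In artery cells these were interferon genes and matrix genes without artery replicate 1 at 3% (adjusted p = 6.53e-05 and 0.00862), oxidative phosphorylation without the pair term (0.0454) and without vein replicate 5 at 3% (0.00548), leukocyte markers with fry (0.0151), and jumonji and TET oxygenases and erythroid markers within set A. In vein cells these were arterial markers (for example 0.00421 without vein replicate 5 at 3%) and venous markers (0.032 with the replicate block). That block let pan-endothelial genes pass between the vessels (0.00788 at 21%, 0.00693 at 3%). Arrays hold no counts, and low signal over background limits the genes near the filter.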

Other observations

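Tests chosen only after the result was seen were those of the numbering of vein cultures. The correlations below are between deviations of arrays from their group means, over all tested genes, and no fit used the shifted numbers.

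In vein cells the arrays at 3% oxygen with numbers 1 to 3 correlated with the arrays of the same number at 21% (0.809, 0.687 and 0.608), but numbers 4 (-0.265) and 5 (0.0126) did not. A candidate explanation is that the numbers above 3 are 1 too low at 3% oxygen, as 5 arrays stand against 6. The extraction protocol counts 24 arrays, 1 more than was used here, and does not say which is absent. Number 4 correlated with number 5 at 21% (0.540) and number 5 with number 6 (0.463), and 1 of 720 assignments, the shifted one, had a summed correlation as high as its 3.11 (1.85 as numbered). Array batches alone are argued against, since 1 of 24 assignments within spike-in set B was as high as the shifted one. A swap of numbers 4 and 5 is argued against by the correlation of number 5 with number 4 at 21% (-0.062). Between vessels at 3% oxygen, vein number 4 correlated with artery number 5 (0.614, against -0.0303 with its own number) while vein number 5 correlated best with artery number 1 (0.233), above artery number 6 (0.169) and its own number (-0.048), so this array gives no such match between vessels. This remains a hypothesis, found and tested on the same arrays.

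A further hypothesis was that artery pairs with a larger rise of cell cycle genes would have a larger fall of p53 and senescence genes, as p53 targets such as CDKN1A hold back division. The result was negative. Across 6 pairs Pearson's r was -0.361 (exact two-sided permutation p = 0.494) and Spearman's rho 0.0857 (exact p = 0.919), and r was 0.708 without the 2 pairs farthest from the median. This was the 1 relation tested.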
